A study of Anolis chlorocyanus and Anolis cybotes and Anolis osa with 24 samples.

How the data were processed

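The data were 24 RNA sequencing libraries of jaw and leg muscle from males of 4 Anolis species, with 3 libraries per species and muscle. Per the labels' protocols, total RNA was extracted from whole muscle with Trizol and libraries were made by BGI. The submitters' processing notes name STAR, a spliced read aligner, without a version. The genome build, the annotation and the counting program are not given in the sources used here, and neither is whether counting used the strand. The authors deposited 1 table of raw counts per gene, with 25920 Ensembl-style identifiers and 24 columns. Its column names equal the sample titles, and all 24 columns were used. The deposited values were whole numbers with totals from 1315319 to 1962685 per library, that is, counts with no normalization. In all libraries together, 8688 identifiers had 0 counts. Depth limits what can be seen: 3 counts, the floor used for a count of 0, correspond to between 1.17 and 2.61 CPM in a library, on the TMM-scaled CPM described below.

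Groups were taken from the species and muscle of each label, and replicate numbers from the titles. Each number occurs once in jaw and once in leg within a species (04, 06 and 08 in chlorocyanus, 01, 03 and 08 in cybotes, 04, 05 and 07 in osa, 15, 16 and 17 in sagrei). The labels do not say in words that a number is an animal. Whether the numbers pair the libraries was checked before any calls were compared, by correlating deviations of log2 CPM from the group means. The jaw and leg library of the same number correlated at 0.296 to 0.740 (median 0.445), and those of different numbers in a species at -0.653 to 0.0461. Deviations sum to 0 within a group of 3, so negative values between different numbers follow from positive ones within a number and are no separate evidence. All 24 libraries correlated best with their own number, among the 3 libraries of the other muscle in their species. The numbers were therefore taken to pair the libraries. Blocked counts are given for leg against jaw over all species and within each, for genes called in all 4 species and for the interaction. The sets of genes described come from the fit without the block. The labels do not state how else the replicates differ, so p-values measure the spread between these samples. Replicate libraries of a group differed beyond sampling noise in each of the 24 pairs, with a chi-square per degree of freedom of 7.30 to 61.3, and each was counted as a separate sample.

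Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr over the 8 groups, which left 9123. Libraries were scaled by TMM factors, and CPM values in the text are counts scaled to the usual per-million unit by the TMM-scaled library size. Log2 CPM used a prior count of 2. The quasi-likelihood F-test was fitted to 8 group means, with 16 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Leg against jaw over all species was the mean of the 4 differences within species, the interaction was the test with 3 degrees of freedom that these are equal, and the sign is leg minus jaw throughout. Standard errors are the absolute log2 fold change divided by the square root of F. The blocked fit had a term for each of the 12 title numbers and a leg term for each species, with 8 residual degrees of freedom. Species differences were tested on 12 sums of both muscles of a title number, after filterByExpr over the 4 species. Shares of counts for single libraries have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only because reads without molecular identifiers are not independent molecules. A table of simulated counts with 200 genes changed by known folds was fitted by the same functions. Its libraries were drawn independently, with no effect shared by the libraries of a title number. The rates of recovery therefore hold for unpaired libraries and not for the paired data, and with the block 37.3% of genes changed 2-fold over all species were recovered. For leg against jaw over all species the fit recovered 14.9%, 53.7% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold. Within 1 species it recovered 5.97% at 2-fold and 40.9% at 4-fold, and for species differences 13.4% and 75.8%.

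Designs, alternatives and the rule for named genes were set before the data were examined. That rule took the genes with a symbol and the largest changes in each direction among those past the threshold, with at least 5 CPM in the higher muscle and the same sign in 12 of 12 pairs. Since the table pairs its identifiers with no symbols, 2 genes in each direction are named by the same criteria. For the same reason the 27 gene lists fixed beforehand, their tests and the composition of myosin heavy chains were not analysed here. Alternatives were 3 other scalings (median-ratio size factors, upper quartile, and library sizes without the 20 most abundant genes), DESeq2 1.42.0, limma voom 3.58.1, no low-count filter, a stricter filter of 5 CPM in 3 libraries, the block as fixed and as random effect, an additive model, fits to single species and leaving out each library. Thinning of leg libraries to the jaw totals, with and without the block, and leaving out both libraries of chlorocyanus 08 or of cybotes 08 were added after the data were examined. Figures were drawn with matplotlib 3.10.9.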

Results

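Gene expression was measured by RNA sequencing in whole jaw and leg muscles of male lizards of 4 species of the genus Anolis. The species were Anolis chlorocyanus, A. cybotes, A. osa and A. sagrei. The 24 libraries fell into 8 groups of 3, a jaw group and a leg group for each species. Within a species the jaw and leg libraries carried the same numbers in their titles, which gave 12 numbered pairs. The series concerned expression and the contractile physiology of muscle, and its stated comparison was 12 leg muscles against 12 jaw muscles. Total counts per library ranged from 1315319 to 1962685. Jaw libraries held 1436590 ± 132821 counts and leg libraries 1602450 ± 143717 (SD, n = 12). The leg total was the higher in 12 of 12 pairs (exact sign-flip permutation p = 0.000488). Leg libraries also detected more genes, 12409 ± 309 against 11717 ± 341, again in 12 of 12 pairs. The 10 most abundant genes of a library took 31.2% ± 3.61 of the counts in jaw and 28.1% ± 3.48 in leg (SD, n = 12), with the leg value higher in 1 of 12 pairs. Genes are given by the identifiers of the deposited table, which pairs them with no symbols.

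Species, muscle and title number all left large marks on the expression profiles. Species accounted for 46.1% of the variance of log2 CPM over the 9123 tested genes, the title number within species for 25.7% and the muscle for 14.1%. The species-by-muscle term took 5.74% and the remainder 8.32%. These shares are not corrected for degrees of freedom, so they do not rank the sources. Species had 3, the title number 8, the muscle 1, the species-by-muscle term 3 and the remainder 8. The components PC1 and PC2, with 19.1% and 15.9% of the variance, separated species. PC3, with 14.3%, placed every jaw library above every leg library.

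**Figure D1:**
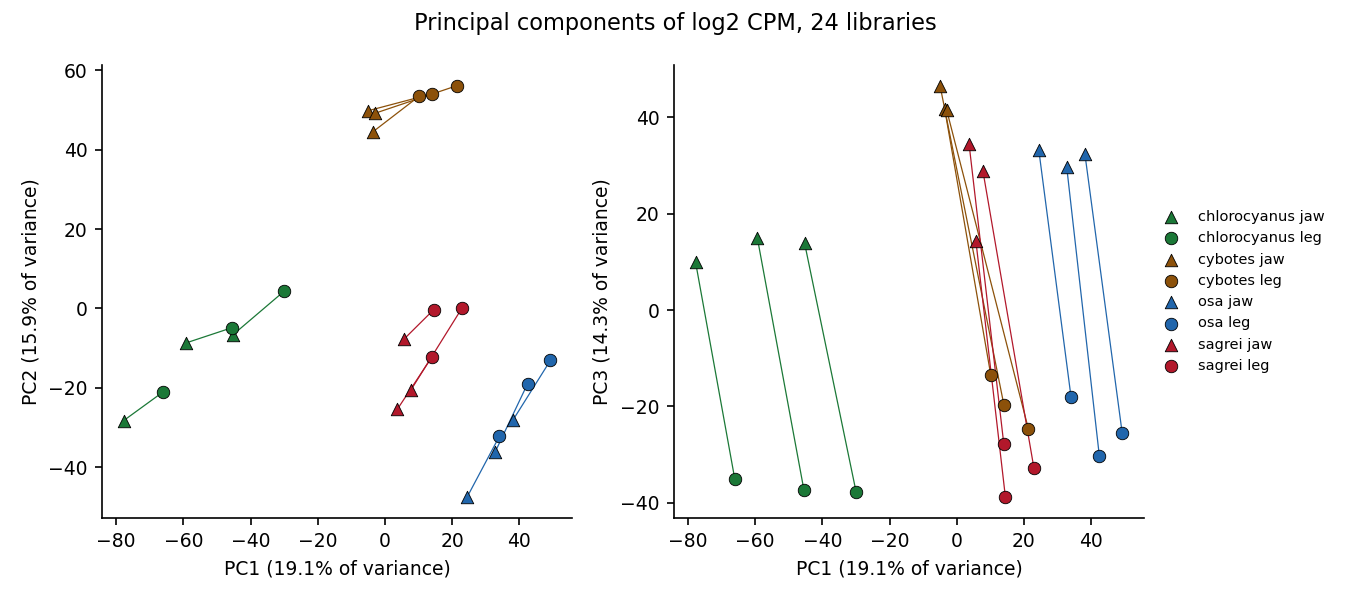
Principal components of log2 CPM in 24 libraries, with PC1 against PC2 (left) and PC1 against PC3 (right); axes are component scores. Triangles are jaw and circles leg libraries, colours are species, and lines join libraries with the same title number. All 12 jaw libraries lie above 0 on PC3 (14.3% of the variance) and all 12 leg libraries below.

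The first comparison asked which genes differed between leg and jaw muscle over the 4 species. Genes that differed made up a sizeable part of the counts of each muscle. The 600 genes higher in leg held 15.8% ± 2.74 of the counts of leg libraries and 1.80% ± 0.192 of those of jaw libraries (SD, n = 12). The 427 genes lower in leg held 5.34% ± 0.549 of leg counts and 21.6% ± 2.79 of jaw counts. These groups were picked on the same libraries, so the shares describe them and test nothing further. Changes of at least 2-fold were more often toward leg, with 440 genes higher and 157 lower. At least 8-fold changes were seen in 72 genes higher and 27 lower in leg, and at least 32-fold changes in 28 and 8. The direction went with abundance. Among 2849 genes with a mean under 10 CPM, 207 were higher and 65 lower in leg. Among 1227 genes over 100 CPM, 66 were higher and 156 lower, and 18.1% of that class was called. The 5047 genes in between had 327 higher and 206 lower.

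The 2 genes with the largest increase in leg were nearly absent from jaw muscle. ENSACAG00000010855 stood at 51.9 ± 21.9 CPM in leg (SD, n = 12), while the 12 jaw libraries together held 1 count. The ratio of pooled counts per total was 923, with an exact 95% interval of 165 to 36507. ENSACAG00000006412 reached 26.7 ± 11.7 CPM in leg and had 0 counts in all 12 jaw libraries. Set against a floor of 3 counts over the jaw group, its level was 162.56-fold higher in leg. The lower end of the exact 95% interval of its ratio was 131.759. The intervals and the floor cover counting error only. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.62e-11 for the former and 2.19e-09 for the latter.

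By the fit of 8 group means and the criteria for named genes, the 2 genes with the largest decrease were ENSACAG00000006784 and ENSACAG00000011927. ENSACAG00000006784 fell from 723 ± 199 CPM in jaw to 5.97 ± 11.9 CPM in leg (SD, n = 12), a log2 fold change of -7.71 (SE 0.42, edgeR adjusted p = 6.76e-12). ENSACAG00000011927, the second most abundant gene by its mean over jaw and leg libraries together, averaged 89152 ± 27558 CPM in jaw against 1811 ± 3852 CPM in leg. Its log2 fold change was -7.38 (SE 0.66, edgeR adjusted p = 2.32e-08). The log2 fold change was -8.14 with the title number as a block, -8.21 by limma voom with or without the block as a random effect, and -8.23 without the osa 07 leg library. Its leg mean rested largely on the cybotes 08 leg library, which stood at 13585 CPM, and was 741 ± 1094 CPM over the other 11. The leg mean of ENSACAG00000006784 was 2.61 ± 2.41 CPM over those 11. All 4 named genes moved in the stated direction in 12 of 12 pairs, which the rule for naming them required. The most abundant gene by that mean, in contrast, averaged 64636 ± 15797 CPM in jaw and 67536 ± 14483 CPM in leg (SD, n = 12), with a log2 fold change of 0.07 (SE 0.19, edgeR adjusted p = 0.916). The third most abundant had a log2 fold change of -0.26 (SE 0.21, edgeR adjusted p = 0.553).

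Of the 9123 genes tested, 1027 passed an adjusted p of 0.05. Among these, 932 had the same sign in all 4 species and 510 in all 12 pairs, 261 upward and 249 downward in leg. With the title number as a block the count was 2268, of which 1212 were higher and 1056 lower in leg. All 1027 genes were among them and none changed direction. At 2-fold or more the blocked fit called 716 genes, 544 higher and 172 lower.

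**Figure D2:**
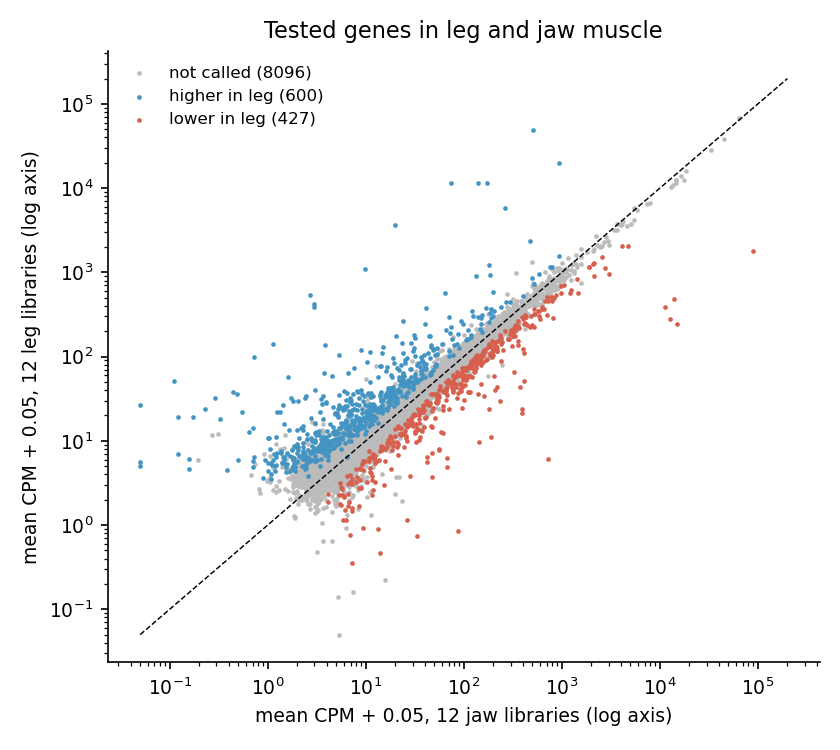
Mean CPM of 9123 tested genes in 12 jaw libraries (x axis) and 12 leg libraries (y axis), both on log axes after adding 0.05; the dashed line marks equal levels. Blue points are the 600 genes higher in leg, red points the 427 lower in leg and grey points those not called.

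Muscle-restricted genes were defined on these libraries as called genes with an absolute log2 fold change of at least 5, a mean of at least 5 CPM in their own muscle and the same direction in 12 of 12 pairs. The 8 jaw-restricted genes held 13.1% ± 2.95 of jaw counts and 0.325% ± 0.659 of leg counts (SD, n = 12). Without the cybotes 08 leg library the leg share was 0.144% ± 0.213 (n = 11). The 28 leg-restricted genes held 9.72% ± 2.03 of leg counts and 0.103% ± 0.123 of jaw counts. Of the jaw set, 5 genes exceeded 1000 CPM in jaw, and of the leg set, 7 exceeded 1000 CPM in leg. Single genes made up much of these shares. The jaw set includes ENSACAG00000011927, at 89152 CPM in jaw, and the leg set a gene at 48503 CPM in leg. In chlorocyanus, osa and sagrei all 8 jaw-restricted genes were called on their own, and 5 were in cybotes. The leg-restricted genes were called in 27 of 28 cases in chlorocyanus and cybotes and in all 28 in osa and sagrei.

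As a ratio of highest to lowest share, the level of these genes varied far more in the opposite muscle than in their own. In percent of counts the SD was larger in their own muscle. The jaw set held between 0.00382% of counts in the osa 04 leg library (exact 95% binomial interval 0.00290% to 0.00493%) and 2.32% in the cybotes 08 leg library (2.29% to 2.34%). ENSACAG00000011927, a member of the jaw set, stood at 15.1 CPM in the former library and 13585 CPM in the latter. The medians of the leg libraries were 0.505% in cybotes, 0.0350% in osa, 0.0230% in chlorocyanus and 0.0184% in sagrei. These 4 groups of 3 did not differ past the threshold (exact permutation p = 0.0669, and 0.0669 after Benjamini-Hochberg adjustment over both sets). The leg set held 0.281% ± 0.130 of counts in cybotes jaw (SD, n = 3), where the lowest library stood at 0.149%. The other 9 jaw libraries reached at most 0.0778%. That share differed between species (exact permutation p = 0.00351, adjusted 0.00701), in a comparison chosen after the values were seen. Both chlorocyanus 08 libraries had the lowest share of their own set, 6.14% in jaw and 5.13% in leg. Those same libraries had the highest TMM factors, 1.298 and 1.317.

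**Figure D3:**
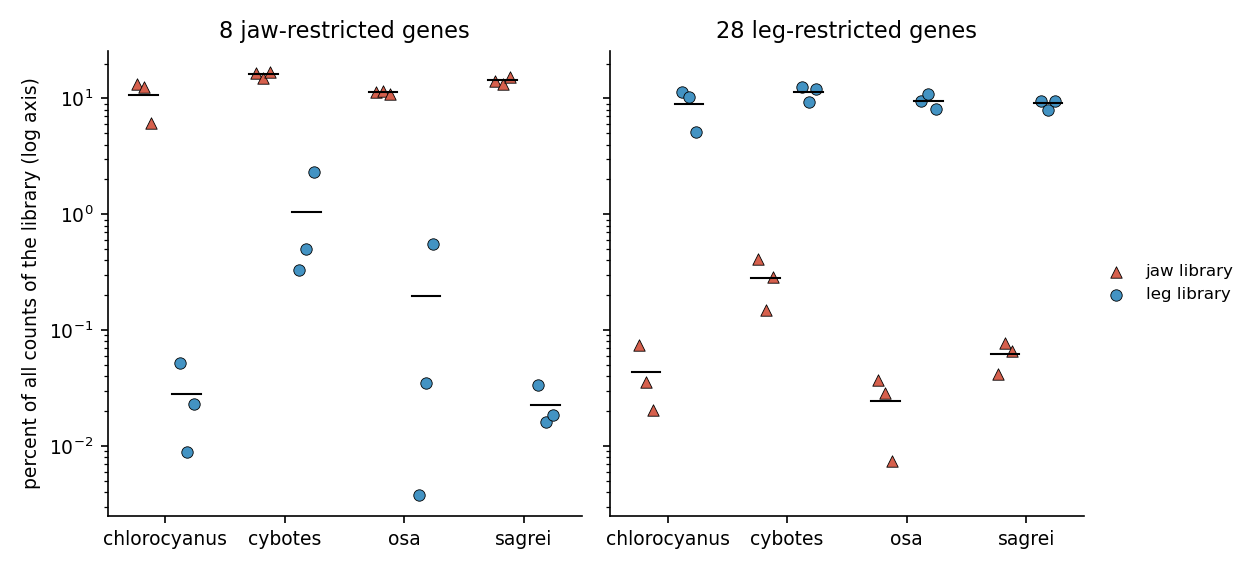
Percent of a library's counts, on a log axis, held by 8 jaw-restricted genes (left) and 28 leg-restricted genes (right) in each species. Triangles are jaw and circles leg libraries, and bars are means of 3. The cybotes 08 leg library stands at 2.32% for the jaw set, the highest of the 12 leg libraries.

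Within each species, the comparison asked which genes separated its own leg and jaw muscles. Cybotes had 208 genes higher and 87 lower in leg, osa 97 and 73, chlorocyanus 93 and 68, and sagrei 85 and 68. A core was shared by all 4 species. It consisted of 61 genes, 42 higher and 19 lower in leg, out of 467 called in any species. With each species fitted alone it was 24 genes, and without a low-count filter 94. Lists drawn independently in each species would share 0.000249 genes, although the 4 contrasts share each gene's estimate of spread. The 42 genes higher in leg throughout had a median log2 fold change of 5.95 and held 11.9% ± 2.46 of leg counts against 0.204% ± 0.130 of jaw counts (SD, n = 12). The 19 genes lower throughout had a median of -3.75 and held 11.04% ± 2.58 of jaw counts against 0.264% ± 0.490 of leg counts, or 0.130% ± 0.158 without the cybotes 08 leg library (n = 11). With 89152 CPM in jaw, ENSACAG00000011927 was among these 19 genes and made up much of their jaw share. For osa and sagrei, 57 genes were higher in leg and 36 lower in both, against 0.904 and 0.544 if the lists were independent. Across all 9123 genes, Spearman's rho between the fold changes of 2 species ranged from 0.260 for chlorocyanus and osa to 0.451 for osa and sagrei, with a median of 0.356 over the 6 pairs. The median was 0.210 without the low-count filter and 0.809 over genes called in either species, a selection that raises it. Genes are not independent replicates, and no library enters more than 1 of the 4 contrasts.

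Totals by species were 161 genes in chlorocyanus, 295 in cybotes, 170 in osa and 153 in sagrei by the edgeR quasi-likelihood test, with 3 libraries a side. Fitted alone, chlorocyanus had 33 genes. Without a low-count filter cybotes had 510, osa 270 and sagrei 280. With the title number as a block they were 740 (392 higher, 348 lower in leg), 1384 (753 and 631), 863 (451 and 412) and 762 (405 and 357). The block then gave 202 genes called in all 4 species, 118 higher and 84 lower, and 38 called in opposite directions. With it, 2270 genes were called in any species. With the block as a random effect the counts were 565, 1144, 695 and 589, and the share higher in leg was 46.6% in chlorocyanus, 47.5% in osa and 48.0% in sagrei. The counts depended on single libraries. Without both 08 libraries of the species, chlorocyanus had 98 genes and cybotes 83. Without chlorocyanus jaw 06 that species had 82 genes. Without chlorocyanus jaw 08 it had 126, and most of these were lower in leg (53 higher, 73 lower). Cybotes had 129 to 187 without jaw 01, 03 or 08 or leg 03 or 08. Osa had 96 to 109 without leg 04 or 05 or any of its jaw libraries, and sagrei had 88 without jaw 16 and 100 without leg 17.

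**Figure D4:**
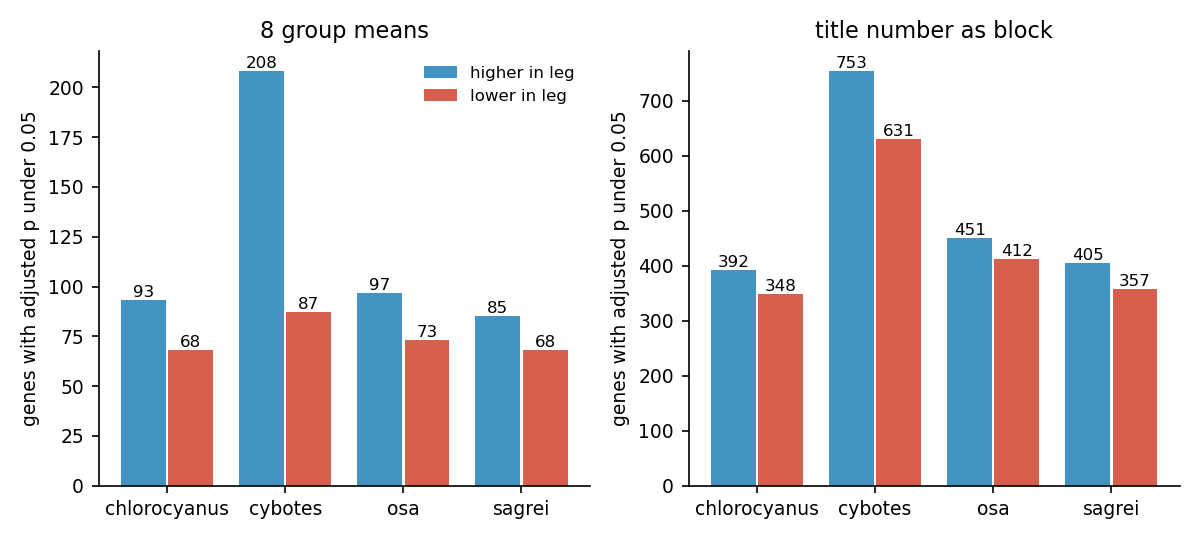
Number of genes with an adjusted p under 0.05, higher (blue) or lower (red) in leg than in jaw, in each species. The left panel is the fit of 8 group means and the right panel the fit with the title number as a block, on different y axes. Cybotes has the most in both, 208 and 87 on the left and 753 and 631 on the right.

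Whether the difference between leg and jaw itself varied among species was tested by the interaction of muscle and species. Without the block a single gene passed, ENSACAG00000012034, named here after its values were seen. In chlorocyanus it stood at 337 ± 98.7 CPM in jaw and 38.6 ± 10.5 CPM in leg (SD, n = 3), and in cybotes at 320 ± 20.4 and 92.3 ± 17.6 CPM. Osa had 109 ± 24.8 CPM in jaw and 67.6 ± 17.1 CPM in leg. Sagrei had 38.4 ± 7.87 and 34.4 ± 4.49 CPM. The log2 fold change from jaw to leg was -3.11 (SE 0.29) in chlorocyanus, -1.80 (SE 0.28) in cybotes, -0.69 (SE 0.27) in osa and -0.16 (SE 0.28) in sagrei. Its mean level thus ran over a wider range among the jaw groups than among the leg groups. The edgeR adjusted p of the interaction was 0.00693, and 0.000128 with the title number as a block. Without the chlorocyanus 06 leg library it was 0.0700.

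At an unadjusted p under 0.05 the interaction without the block counted 393 genes, where 456 would pass by chance. That fit leaves the spread between title numbers in its residual, although leg and jaw are compared within numbers. Its p-values therefore tend to be too high, and the shortfall below 456 is no evidence against an interaction. DESeq2 called 39 genes, limma voom 5 and edgeR without a low-count filter 75. The edgeR test called 4 genes without chlorocyanus leg 08 or sagrei jaw 17, and 5 without both chlorocyanus 08 libraries. It called 2 without chlorocyanus leg 04 or jaw 08, osa leg 05, or sagrei jaw 15 or leg 15. With the block, edgeR called 272 genes (150 with the block as a random effect), and 1650 had an unadjusted p under 0.05. Of the 272, 161 were also called for leg against jaw in the blocked fit. By estimated fold changes alone, called or not, 50 of the 272 rose at least 2-fold in 1 species and fell at least 2-fold in another. The species farthest from the mean of the other 3 was cybotes for 97 genes, chlorocyanus for 80, osa for 48 and sagrei for 47. Between single pairs of species, at most 2 genes were called for any pair without the block, while the blocked difference called 170 genes for chlorocyanus and cybotes and 21 for osa and sagrei, the highest and lowest of the 6 pairs. Simulated libraries were drawn independently, without the pairing by title number seen in the data. In them the unblocked interaction test recovered 13.6% of genes changed 4-fold in a single species and none of those changed 2-fold.

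**Figure D5:**
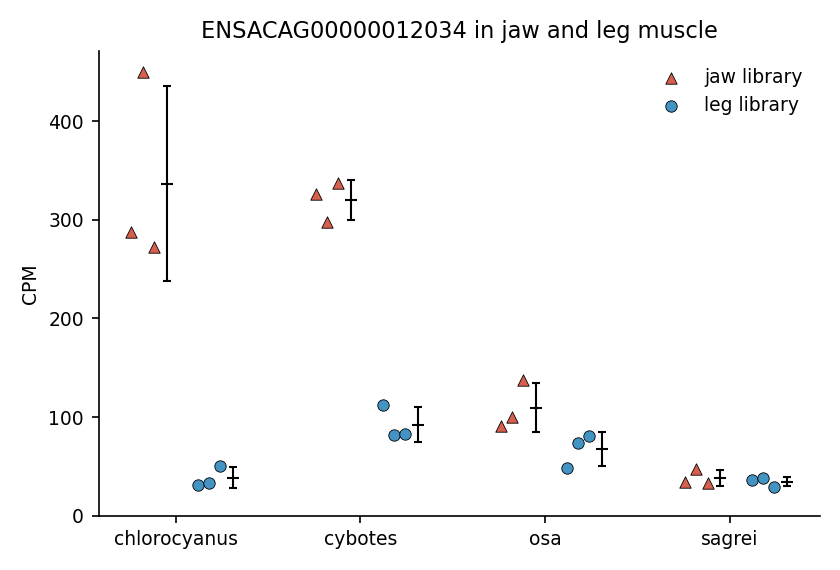
CPM of ENSACAG00000012034 in each library, by species, with triangles for jaw and circles for leg. Black bars are the mean ± SD of 3 libraries. Jaw means run from 38.4 CPM in sagrei to 337 CPM in chlorocyanus, and leg means from 34.4 to 92.3 CPM.

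Species differences were tested on the jaw and leg counts summed within each title number, 3 sums per species. They were widespread, with 4344 of 9908 genes (43.8%) past an adjusted p of 0.05 by the edgeR quasi-likelihood test. Chlorocyanus and osa differed most, at 2432 genes, 1176 higher and 1256 lower in osa. Osa and sagrei differed least, at 1351 genes, 643 higher and 708 lower in sagrei. The jaw libraries alone gave 3327 of 7805 genes and the leg libraries alone 2869 of 8568. Both muscles called 1926 of the 7602 genes tested in each, where independent lists would share 1076. The jaw and leg libraries are paired by number and share deviations of single numbers, which this expectation leaves out. Among genes called for leg against jaw, 417 were also called for species, out of 9086 tested in both, where independent lists would share 459. Reads were counted on identifiers common to the 4 species, so a sequence difference that alters mapping cannot be separated here from a difference in expression.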

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

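The split counts below were planned before the data were examined. The gene ENSACAG00000012034 was singled out because its difference between leg and jaw differed among species, by a test of that difference with 3 degrees of freedom (edgeR adjusted p = 0.00693). The fall from jaw to leg was deepest in chlorocyanus, at -3.11 on the log2 scale, and nearest to 0 in sagrei, at -0.16. Over the other settings its adjusted p ran from 3.17e-09 (DESeq2) to 0.0313 (both cybotes 08 libraries left out). It was 0.0700 without the chlorocyanus 06 leg library, where the count for the interaction was 0 by edgeR and 370 of 9596 genes had an unadjusted p under 0.05. The count of 1 gene is not distinguishable from chance: 18 of 100 assignments of the 12 title numbers to species, the real assignment included, called as many genes, and the highest of the others called 2. No explanation for this gene was tested.

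With the title number as a block, 272 genes differed among species in their leg minus jaw difference, which is why this result stands here. In 1 of 100 assignments of the numbers to species, the real one, the blocked count was this high, and the highest of the others was 38, so chance assignment is excluded at this number of draws. The block removes the spread between title numbers, which takes 25.7% of the variance. The blocked interaction was not refitted without any library or number. Cybotes was the farthest species for 97 of the 272 genes. Whether jaw-restricted transcripts in its leg libraries, or leg-restricted ones in its jaw libraries, shaped these calls was not tested.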

How the results depend on the processing

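Thinning and the joint removal of both libraries of chlorocyanus 08 or cybotes 08 were chosen after seeing the data. The 4 genes named for leg against jaw stayed past the threshold in the same direction under all of their settings. By limma voom the log2 fold change of ENSACAG00000010855 was 6.87, against 8.72 in the main fit. For ENSACAG00000006412 it was 6.06 against 8.28. The cause of the moves below was not tested, with exceptions that follow from the design. The block takes the spread between title numbers out of the residual. Fewer libraries or a fit to 1 species leaves less information, but this does not account for every such move. Fitted alone, osa rose from 170 to 221 genes, while cybotes fell from 295 to 267 and sagrei from 153 to 129. Without both chlorocyanus 08 libraries, cybotes rose to 421, osa to 211 and sagrei to 221. Gene lists and myosin composition were not run, as the identifiers carry no symbols.

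Leg against jaw over all species gave 1027 genes, 2268 with the replicate block, 2185 with the block as a random effect and 2216 with the block and thinning. Those 3 settings gave 740, 565 and 745 in chlorocyanus, 1384, 1144 and 1331 in cybotes, 863, 695 and 824 in osa, 762, 589 and 747 in sagrei, and 272, 150 and 274 for the interaction. In cybotes the share of calls higher in leg fell from 70.5% to 54.4% with the block, and with the random effect most calls were lower in leg in 3 species: the share higher fell from 57.8% to 46.6% in chlorocyanus, from 57.1% to 47.5% in osa and from 55.6% to 48.0% in sagrei. Without chlorocyanus jaw 08 that species also turned, to 42.1%. Without a low-count filter cybotes had 510 genes, osa 270, sagrei 280, the interaction 75 and the genes called in all 4 species 94. Fitted alone, chlorocyanus had 33 genes, and 24 genes were called in all 4 species. Without both chlorocyanus 08 libraries it had 98 and the interaction had 5, and without both cybotes 08 libraries cybotes had 83. For the interaction DESeq2 called 39 and limma voom 5. Species differences gave 2869 genes in leg libraries alone. The median rho between species was 0.210 without a filter and 0.809 over genes called in either species, a selection that raises it.

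In fits without the block, leaving out each library in turn gave 892 to 1127 genes over all species. It gave 82 to 167 in chlorocyanus, 129 to 342 in cybotes, 96 to 189 in osa, 88 to 178 in sagrei and 0 to 4 for the interaction. Leaving out each number gave 3652 to 4784 genes for species. At this depth and with 3 libraries a side, 5.97% of simulated 2-fold changes within 1 species were recovered, in libraries drawn without the pairing. A gene not called within a species is thus not shown to be equal.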

Other observations

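The tests on the jaw-restricted genes in leg libraries and on neighbouring lines of the table were chosen after their patterns were seen, and the test on depth after the library totals were, while those on scaling and sample splits were set beforehand. Genes that differed between leg and jaw lay together in the deposited table more often than chance placement gives. The order of the table is not explained in the sources used here and is not that of the identifiers. Of the 600 genes higher in leg, 78 pairs were neighbours among the tested genes, against a mean of 39.3 over 10000 random placements, and of the 427 genes lower in leg, 46 pairs against 19.98. None of those placements reached either count. The 28 leg-restricted genes formed 11 neighbouring pairs against a mean of 0.0839, with runs of 7, 4 and 3 genes. The 8 jaw-restricted genes formed none, against a mean of 0.0055.

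The run of 7 holds the most abundant leg-restricted gene, its sixth member, at 48503 ± 15690 CPM in leg (SD, n = 12), and the second member at 11477 ± 6300 CPM. The remaining members average 36.05 to 535 CPM in leg. All 7 have a log2 fold change of at least 6.91, and the highest is 7.91. Chance placement is excluded, since none of 10000 random placements gave as many neighbouring pairs (permutation p = 1e-04, the smallest they can give). Reads shared with a more abundant member would keep a member's counts in a fixed ratio to it within a species. This stays open for all 6 members that have a more abundant one. The ratio varied beyond counting error in the first 4, with a chi-square per degree of freedom of 3.59, 901, 109 and 18.8 in their order, which goes against a fixed ratio most strongly for the second and the third, but no repeat library of a sample was used here to show how far technical noise alone moves a ratio. The fifth and seventh members had a median of 2.13, under a bound that was revised after a first result, and 1 of 10 leg-restricted genes outside the run and in its range of levels passed it too. A group of related genes regulated together may account for the run, a hypothesis that was not tested because no annotation was used here.

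Jaw-restricted transcripts varied widely among leg libraries, from 0.00382% to 2.32% of counts, and exceeded 0.3% in all 3 cybotes leg libraries and in osa 07. If a fixed portion of the jaw library of the same number had been carried over, the 6 jaw-restricted genes over 100 CPM in jaw would stand at 1 ratio to it. After subtracting the highest ratio seen in chlorocyanus and sagrei, the highest ratio was 3.40, 8.99 and 10.5 times the lowest in cybotes 08, cybotes 03 and osa 07, and in cybotes 01 a gene was left with none. For cybotes 08 the value was at least 2.48 against any of the 12 jaw libraries. These values go against carry-over from any single jaw library as the whole source in cybotes 08. In cybotes 01, cybotes 03 and osa 07 they go against the jaw library of the same number only. Other jaw libraries were not compared with those leg libraries. No repeat library was used here to show how far technical noise alone moves a ratio. For cybotes 08, a part of up to 6.85% of the level in its own jaw library is not excluded. The jaw set held 16.95% of the counts of that jaw library, so such a part could be a large share of the 2.32% in the leg library. A mixture of several jaw libraries was not tested. A difference between species (exact permutation p = 0.0669) or between animals in the make-up of the leg muscle could also produce these values and stays open.

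Calls of at least 2-fold were higher in leg in 73.7% of cases. The leg libraries were deeper, but thinned to the jaw totals they gave 73.93%, so depth is excluded as the whole source. Over 3 other scalings the lowest share was 74.04%, so the choice among these scalings is not the source. They differed little from the main one: the median log2 fold change of all genes was 0.01 to 0.04, against 0.008. Scaling by plain library totals was not run, so an effect of a few abundant genes was hardly put to the test. A muscle difference stays possible, as a hypothesis found and tested on the same data.

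Other splits of the same libraries were fitted to see whether chance can be excluded. For leg against jaw over all species, 1 of 100 splits within species, the real one, reached 1027 genes, and the highest of the others called 332, so chance is excluded. That split parted 8 of the 12 numbered pairs, and the 5 other splits that parted all 12 called no gene. With the block, 1 of 100 splits, again the real one, reached 2268, with 109 as the highest of the others, and chance is excluded there too. For species differences 1 of 100, the real one, reached 4344 against 216, which also excludes chance. Within a species there are 10 splits, too few for a share under 0.05. The highest of the others called 0 in cybotes against 295, 0 in osa against 170 and 56 in sagrei against 153, so 1 of 10 reached the real count in each. In chlorocyanus 3 of 10 splits reached the 161 genes of the real one, with up to 437. Those 2 other splits kept the libraries of 2 numbers together and parted 1, which points to the spread between numbers, and the 3 other splits that parted all 3 numbers called 0. The blocked count there was 740.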
